A study of Mus musculus with 319 samples.

How the data were processed

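The series holds 319 mouse samples from the thymus, and each sample is 1 well of a plate. Per the labels, cells were sorted by flow cytometry as UVBlue-, CD11c-, CD45-, EPCAM+, MHCIIlo and Flare25+. Flare25 marks cells that express Il25, an epithelial cytokine made by tuft cells, so the sort aimed at thymic tuft cells. Polyadenylated RNA was made into libraries by Smart-seq2, a full-length protocol without molecular identifiers, with ERCC spike-in RNA in each well. The mice were of a C57BL/6 background, 6 weeks old except for 1 sample of 5 weeks, and their sex is labelled as mixed. The Aire-/- mice lack, by their label, functional Aire, the nuclear regulator that drives expression of tissue antigens in medullary thymic epithelial cells (mTEC). Wild-type (WT) wells came in batch 1 (31 wells of a set called June5 and 95 of a set called June29) and in batch 2 (92 wells). The 96 wells labelled Aire-/- were all in batch 2. There was also a 50-cell well of each genotype in batch 2, 1 no-cell well in batch 1, and 2 no-cell wells in batch 2, which have no column in the deposited tables and were not analysed here.

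The deposited count tables hold counts, whole-number reads per gene and well, in separate tables for wild-type and Aire-/- wells. The submitters' processing notes name STAR, featureCounts 1.5.3 and Subread for alignment and counting and GRCm38 as the genome build, and other versions and the annotation are not given in the sources used here. Each table has 48887 entries, of which 48441 carried a gene name in the reference used here or were 1 of the 92 ERCC spike-ins. A further deposited table holds a score per gene and well, with values from -26.9 to 115 for 14108 genes and 292 wells. The authors do not say how this score was made, the notes name R 3.4.0, and the score entered no value reported here. The list of wells in the score table served only as an alternative choice of cells. A deposited table of 316 wells holds other labels from the authors, namely a plate number and a genotype for each well. Every sample column of the count and score tables was matched to a sample. Gene positions came from the GENCODE M21 annotation of GRCm38.

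Gene reads leave out the spike-ins. A well was kept as a cell with at least 10000 gene reads, at least 1000 genes with a read, and at most 20% of gene reads from mitochondrially encoded genes, and no doublet caller was run, so a well that held more than a single cell could be kept. Counts were summed over the cells of a set and scaled to the gene reads of the set (CPM), with an exact Poisson interval. A cell counted as positive for a gene with 5 or more reads, and the share of positive cells has an exact Clopper-Pearson interval. All intervals are at the 95% level. Reads without molecular identifiers are not independent molecules, so intervals and the limits allowed by a count of 0, which are 3 counts of the total, cover counting error only. The 10th percentile of gene reads, 231697, was the depth to which cells were thinned where that is stated.

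The labels name no animals, and thymi were pooled, so each set of wells is 1 sample without a replicate. No p-value was made from cells, and differences between sets are given with their sizes alone. A gene passed the size rule with a CPM of at least 20 in the higher set, a log2 fold of at least 1 with 1 CPM added to each side, and shares of positive cells at least 15 points apart in the same direction. That rule is not a test. Cells labelled Aire-/- were compared with WT batch 2 only, within the same batch. Plate 1 held Aire-/- wells 1 to 48 and WT wells 49 to 96, plate 2 held WT wells 97 to 140 and Aire-/- wells 145 to 192, and folds are also given within each plate. The counts of genes between wild-type sets, and between plates of a genotype, served as background.

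Before the data were examined, 33 gene lists were fixed. They cover markers of tuft cells, Aire-expressing mTEC, mTEC low, corneocyte-like, neuroendocrine-like, microfold-like and ciliated epithelium, cortical epithelium (cTEC), thymocytes, B cells, dendritic cells or macrophages, fibroblasts and endothelium. They also cover epithelial genes, taste transduction, bitter taste receptors, eicosanoid synthesis, cytokines and chemokines, MHC class I and MHC class II presentation, Aire-dependent and Aire-independent tissue antigens, tuft-1 and tuft-2 signatures, type 2 cytokine receptors, nicotinic and acetylcholine genes, cell cycle, dissociation stress, interferon response, ribosomal proteins, mitochondrially encoded genes, and male and female markers. A list of 23 glycolysis enzymes was added after the data were seen. A list is given by the median log2 fold over members at 5 CPM or more in either set, and by the percentile of that median among 10000 random lists matched on size and expression. A list was called when its percentile lay below 2.5 or above 97.5, which describes these libraries and is not a test across animals.

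The genes named were chosen by a rule fixed before the data were examined. It takes Aire and Il25 in every set, each list member past the size rule with up to 4 more members of each list by level in WT batch 2, and the 10 highest and 10 lowest folds past the size rule with the same sign on both plates. It also takes the 5 highest and 5 lowest folds for each pair of wild-type sets, up to 6 of the top 10 leading genes of each cluster, and the 5 bitter taste receptors in the largest share of cells. Genes within 100 kb of Aire, genes past the size rule on both plates and further members of the glycolysis list were named after their values were seen.

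Clusters were made with scanpy 1.11.5 and leidenalg 0.10.2 from log CPM values of 2000 variable genes, 20 principal components, 15 neighbours and a resolution of 1, with no integration of batches. Leading genes of a cluster needed 5 or more reads in at least 30% of its cells. Alternative scalings were TMM from edgeR 4.0.16 and median-of-ratios size factors from DESeq2 1.42.0 in R 4.3.3. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Reads that several gene copies could share were gauged by the percent of each gene's 31-base words, in its longest transcript, that also lie in transcripts of other genes. Of 31 alternative choices computed, 7 were added after the data were seen.

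The size rule was tested on simulated data, drawn from the profiles of WT batch 2 cells at the depths of the real wells, with planted changes. It found 47 of 50 genes planted at a 4-fold difference through more positive cells and 13 of 50 at a 2-fold difference. Where the same folds were planted as more reads in cells that were already positive, it found 4 of 50 and 3 of 50. Of 21650 genes, 7483 of them at 20 CPM or more in WT batch 2, 4 unchanged genes passed as higher and 7 as lower. A planted list reached percentile 100, and 2% of 100 unchanged lists of 20 genes fell outside the calling limits. The simulated data came from WT batch 2 profiles alone, so these figures do not cover differences between pools. Lists with most of their reads in a single cell were not measured separately. The simulated share is thus no estimate of false calls among the real lists.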

Results

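Messenger RNA was counted in 314 wells that each received 1 sorted cell, in a 50-cell well of each genotype and in 1 no-cell well. Of the single-cell wells, 301 passed the filter, with 29 of 31 in the June5 set, 87 of 95 in the June29 set, 89 of 92 in WT batch 2 and 96 of 96 in the set labelled Aire-/-. The 13 wells left out comprised 12 with too many mitochondrial reads and 1 with too few reads and genes. Median gene reads per cell were 539655 in June5 (range 101578 to 2927690), 1150170 in June29 (157592 to 2827447), 566923 in WT batch 2 (88822 to 1470015) and 638298 in the cells labelled Aire-/- (45266 to 2709942). The median cell had 4639, 5136, 4212 and 4582 genes in these sets in turn, and 4153, 3586, 3776 and 4067.5 after thinning to 231697 reads. Each set was a single pool without replicates, so no value below has an error across animals.

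The wild-type sets show what a sorted thymic tuft cell expressed and how far sets with the same genotype label lay apart. Tuft core genes, summed over the list, came to 27268 CPM in June5, 19970 in June29, 20792 in WT batch 2 and 22562 in the cells labelled Aire-/-. Avil, an actin-binding protein of tuft cells, stood at 4222 CPM in June5, 3432 in June29, 2893 in WT batch 2 and 4126 in the cells labelled Aire-/-, with reads in at least 97.8% of cells of each set. Trpm5, the cation channel of taste and tuft cell signalling, stood at 3080, 2374, 2274 and 1937 CPM. The taste G protein subunit Gnat3 was read in 68.97%, 73.6%, 60.7% and 64.6% of cells, and the adaptor gene Sh2d6 in 100%, 94.3%, 85.4% and 80.2%. Of the 30 tuft core genes, 25, 23, 23 and 24 were found in at least 50% of the cells of the set, and their median level was 507, 350.0, 424 and 414 CPM. The keratin genes Krt8 and Krt18, of simple epithelium, stood at 5694 and 3151 CPM in WT batch 2, and Epcam, the adhesion protein used in the sort, at 1388. Pou2f3, the transcription factor on which tuft cells depend, stood at 432 CPM in WT batch 2 and 456 in the cells labelled Aire-/-. At least 2 tuft core markers were found in every kept wild-type cell and in 95 of 96 cells labelled Aire-/-.

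**Figure D1:**
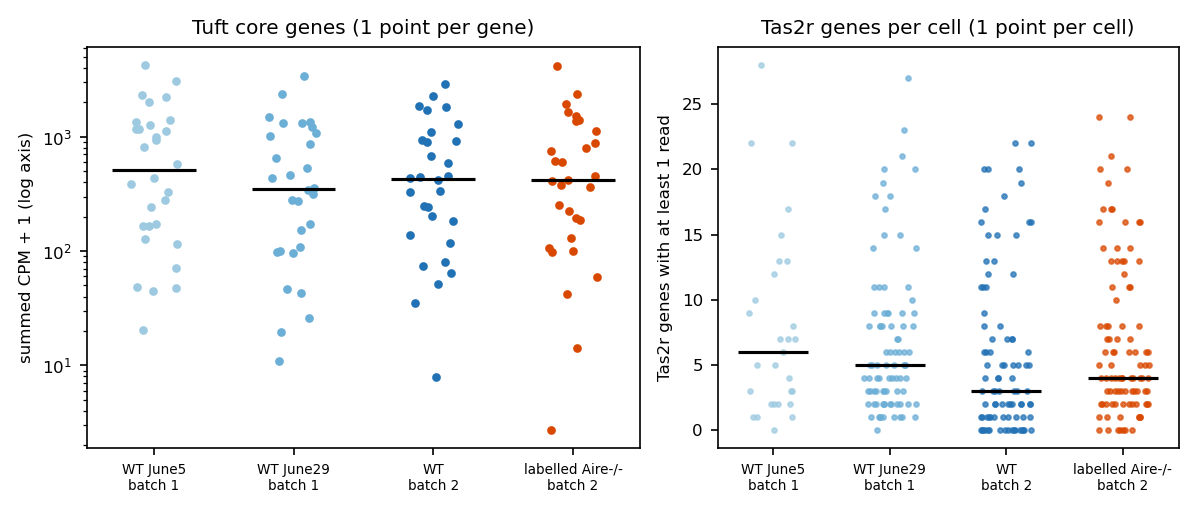
Left, summed CPM (1 CPM added, log axis) of tuft core genes in the 4 sets of single cells, each point a gene and the line their median. Right, number of bitter taste receptor (Tas2r) genes with a read in each cell, 1 point per cell and a line at the median, which was 6 in June5, 5 in June29, 3 in WT batch 2 and 4 in the cells labelled Aire-/-.

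Taste receptors of the bitter family were read in most cells, with many members in some. The median cell had reads of 6 Tas2r genes in June5, 5 in June29, 3 in WT batch 2 and 4 in the set labelled Aire-/-, of 40 Tas2r entries including pseudogenes. Single cells reached 28, 27, 22 and 24 of them. Tas2r108 was read in 55.5% of all kept cells, Tas2r105 and Tas2r117 in 43.2% each, Tas2r138 in 40.9% and Tas2r113 in 33.2%, counting 1 read or more. No Tas2r read was found in 1 of 29, 1 of 87, 17 of 89 (19.1%, interval 11.5 to 28.8) and 7 of 96 cells (7.29%, interval 2.98 to 14.4). The June29 median depended on depth, since it was 3 after thinning, and with 5 reads required the medians were 2, 2, 2 and 3.

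Markers of other cell types were present in part of the cells, including haematopoietic cells, which the CD45- and CD11c- gates should remove. At least 2 markers of 1 haematopoietic list (thymocyte, B cell, or dendritic cell or macrophage) were found in 10 of 29 cells in June5, 29 of 87 in June29, 10 of 89 in WT batch 2 and 12 of 96 labelled Aire-/-. Most of those in batch 1 met the B cell list, with 9 and 23 cells against 5 and 8 in batch 2, and Ebf1, a B cell transcription factor, was read in 44.8% and 70.1% of batch 1 cells against 5.62% and 7.29% in batch 2, at no more than 13.5 CPM in any set. Thymocyte markers were found in 1, 6, 4 and 2 cells and dendritic cell or macrophage markers in 0, 6, 2 and 3. Among epithelial types, Aire-expressing mTEC markers were found in 4, 5, 5 and 16 cells, mTEC low markers in 5, 28, 24 and 32, cTEC markers in 6, 17, 14 and 19, and corneocyte-like markers in 0, 3, 5 and 3. Microfold-like markers were found in 13, 37, 18 and 21 cells, led by Gp2, a receptor for bacteria, at 1291, 839, 531 and 564 CPM. Ciliated markers were found in 4, 13, 17 and 16 cells and neuroendocrine-like markers in 0, 3, 3 and 3. Fibroblast markers were found in 0, 2, 0 and 0 cells and endothelial markers in 0, 0, 2 and 1, and a count of 0 of 96 allows a share of up to 3.13%. These shares rest on how many reads and markers are required.

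Wild-type sets, which differ in batch or day and also in sex composition, gave more genes past the size rule than the genotypes did. Cells with Xist alone and with Y-linked genes alone numbered 7 and 13 of 29 in June5, 0 and 66 of 87 in June29, and 42 and 30 of 89 in WT batch 2. June29 against June5 gave 1.81% of 8358 genes higher and 3.398% lower, WT batch 2 against June5 gave 1.90% and 3.97% of 8561, and WT batch 2 against June29 gave 3.38% and 2.68% of 8513, with 1.02% and 0.399% of 8267 between the genotypes. Xist, the RNA of the inactive X chromosome, stood at 470.2 CPM in June5, 1.10 in June29 and 279 in WT batch 2. June29 was also lower than June5 in Gba2, Kiz, Lsamp and Mlh3, and higher in Trmt2a (0 to 72.3 CPM), Ahnak, Gpatch2, Mtm1 and Slc2a4rg-ps. WT batch 2 was lower than June5 in Mfsd2a, Gm12164, Gm20594, Gm7899 and Acta1 (55.4 to 1.55 CPM), and higher in Ddo, Elp3, Usp40, Ttc17 and Trmt2a. Against June29, WT batch 2 was lower in Gm10801 (1783 to 18.8 CPM), Gm26870, Gm10717, Gm10718 and Gm10719. It was higher in Gapdh, a glycolysis enzyme (18.8 to 444.6 CPM), the ribosomal protein gene Rpl21 (9.36 to 208), Gm8815, Hist1h2bn and Xist. Genes with at least 30% of their words in other genes had a median log2 fold of 0.31 in this pair, against 0.09 for genes with under 5%. The ribosomal list had a median of 1.35 in the same pair.

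The comparison of cells labelled Aire-/- with WT batch 2 asks how thymic tuft cells differ where Aire is disrupted. Aire itself was higher in the cells labelled Aire-/-, at 152.7 CPM (interval 149.9 to 155.6) against 18.9 (17.8 to 20.1). It was read in 32 of 96 of those cells (33.3%, interval 24.04 to 43.7) and in 7.87% of WT batch 2 cells (interval 3.22 to 15.5). The log2 fold was 2.95, with 2.44 on plate 1 and 3.22 on plate 2. A single cell labelled Aire-/- held 43.4% of the Aire reads of its set, and the fold without it was 2.17. June5 and June29 cells had Aire at 7.84 and 11.2 CPM. Counts per gene cannot show which exons were read, so they do not tell a disrupted transcript from an intact one. Il25, the gene reported by the sort, stood at 70.4, 42.4, 72.9 and 96.1 CPM across the 4 sets, with a log2 fold of 0.39 between genotypes.

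Between the genotypes 84 genes were higher and 33 lower by the size rule, out of 8267 genes at 20 CPM or more. On the same rule plate 2 had 0.627% of genes higher and 3.12% lower than plate 1 within WT batch 2, and 0.817% and 2.17% within the cells labelled Aire-/-. Of the 84 and 33 genes, 81 and 33 had the same sign on both plates. When each plate was taken alone, genes equal to 2.65% of those 8267 were higher and 1.46% lower on plate 1, and 3.73% and 1.32% on plate 2. Of these, 24 higher and 11 lower genes passed on both, where independent plates would share 9.35 and 1.83 if every gene were equally likely to pass. Genes differ in level and in share of positive cells, so these figures can be too low. Both plates hold cells of the same pools, so a gene shared by them is not replicated across animals. Across genes, which are not independent replicates, the folds of the plates correlated at 0.241.

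Among the genes with the highest folds were Dnmt3l, a cofactor of DNA methylation that lies next to Aire (0.105 to 87.4 CPM, log2 fold 6.32, read in 1.12% and 20.8% of cells), and the fucosyltransferase gene Sec1 (1.08 to 55.9 CPM, 4.77). The transferrin receptor gene Tfrc was higher by the rule (3.86 to 42.97 CPM, 3.18), but June5 and June29 cells stood at 49.8 and 47.2 CPM, and against the median of the 3 wild-type sets the fold was -0.13. Zcchc18 (3.42), Ess2 (2.95), the translation factor gene Eif2b3 (2.87), the ubiquinone synthesis gene Coq3 (2.55), the epithelial calcium-binding protein gene S100a14 (2.23) and Alg2 (2.18), of N-glycan synthesis, were also higher. S100a14 had 55.2% of its reads in the same cell that held most Aire reads, and its fold without that cell was 1.12. The lowest folds were those of Enpp2, which encodes autotaxin (216 to 1.963 CPM, -6.19), and of the Y-linked genes Uty and Eif2s3y (36.3 and 30.9 CPM in WT batch 2 against 3 and 2 reads in all cells labelled Aire-/-). That is a ratio of 876 for Uty (counting interval 299 to 4252) and 1117 for Eif2s3y (309 to 9233). Naaladl2 (-2.97), Ercc6l2 (-2.94), Gm42609 (-2.75), Atp5s (-2.72), Zc3h4 (-2.71), the glucocorticoid receptor gene Nr3c1 (-2.44) and Gipc2 (-2.29) were lower as well. Without the cell with most reads in the higher set, Enpp2, Naaladl2, Zc3h4 and Tfrc no longer passed the rule. Their folds of -5.85, -2.48, -2.29 and 2.93 were still past the fold limit. They thus failed on the level or on the shares of positive cells, and not on the fold. Past the rule on both plates were, among the genes already named, Aire, Sec1, Ess2, Coq3, S100a14, Ercc6l2, Nr3c1 and Gipc2, together with Cbln4 (54.5 to 190.4 CPM), Psmd1 (44.8 to 162.8), Card10 (95.8 to 24.6) and Alg13 (148.2 to 49.02), chosen after their values were seen. Sex-linked reads separated the sets, with 5 reads as the limit for Xist and for the Y-linked genes. Of 96 cells labelled Aire-/-, 86 reached it for Xist alone and 0 for Y-linked genes alone, and WT batch 2 held both kinds of cells.

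**Figure D2:**
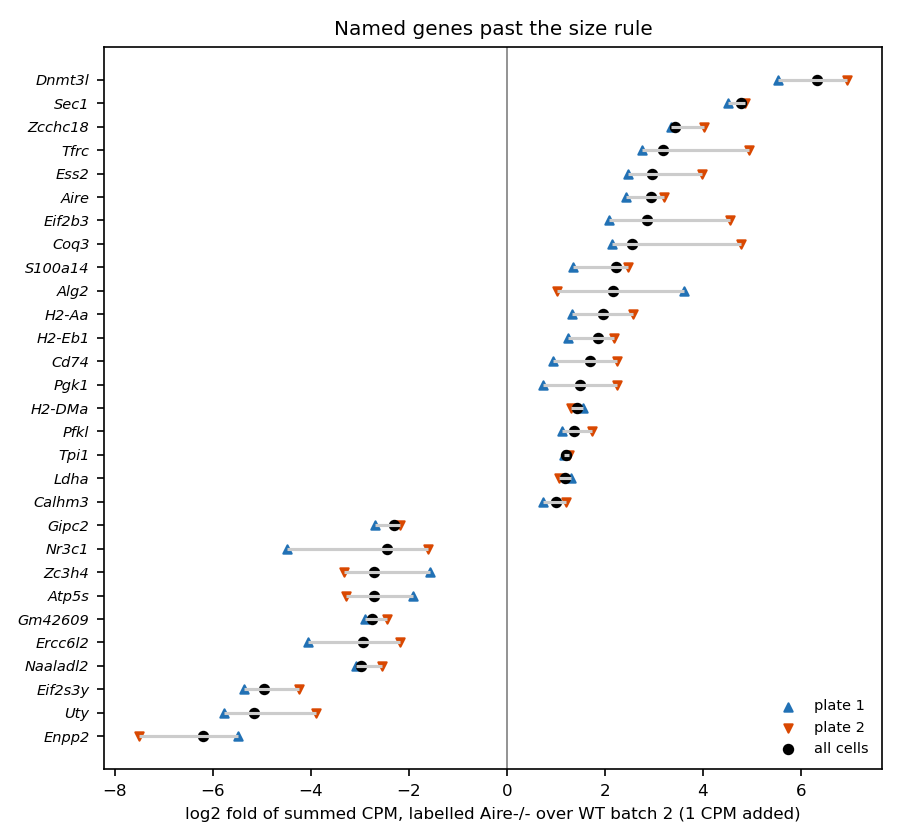
Log2 fold of summed CPM, cells labelled Aire-/- over WT batch 2 with 1 CPM added, for the 29 named genes past the size rule, with circles for all cells and triangles for each plate. Dnmt3l has the highest fold (6.32; 5.53 on plate 1 and 6.93 on plate 2) and Enpp2 the lowest (-6.19).

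MHC class II presentation genes, whose products show peptides to CD4 T cells, were higher in the cells labelled Aire-/- although the sort took MHCII low cells in both genotypes. Summed reads of the 11 list members came to 6712 CPM (interval 6693 to 6731) against 2101 (2089 to 2113) in WT batch 2, 1218 in June5 and 2793 in June29. The 50-cell wells went the other way, at 9699.8 CPM in the WT well and 4965 in the Aire-/- well, and the no-cell well stood at 2527 CPM from 25 reads. Members higher by the size rule were H2-Aa (331 to 1301 CPM, read in 44.9% and 73.96% of cells), H2-Eb1 (344 to 1246), the invariant chain gene Cd74 (666 to 2149) and H2-DMa (37.3 to 102.9), which helps to load peptides. H2-Ab1 stood at 526 and 1526 CPM with a share gap under the rule. The list median was 1.65, at percentile 100 of random lists, with 0.94 on plate 1 and 1.82 on plate 2, and 10 of 11 members were positive. Between wild-type sets it was 1.35 for June29 against June5, 0.69 for WT batch 2 against June5 and -0.24 for WT batch 2 against June29. A single cell labelled Aire-/- on plate 2 held 45.4% of the list's reads in its set. Without it the summed reads stood at 3761 CPM, the list median was 0.81, H2-Aa (1.199) and H2-DMa (1.17) still passed the rule, and H2-Eb1 (1.00) and Cd74 (0.81) did not. That cell had few tuft core reads, with 1622 CPM of the list against 23122.5 in the other cells of its set, and it held 6 of the 8 Aire-expressing mTEC markers at 5 or more reads. Whether it is a tuft cell, an Aire-expressing mTEC or more than 1 cell is not known. The median cell, on which a single cell has no hold, had 1935 CPM of these genes (interval 1499.8 to 3053) against 710.4 in WT batch 2 (520.4 to 1056). On plate 1 the medians were 1964 and 547, and on plate 2 they were 1935 and 975.3.

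**Figure D3:**
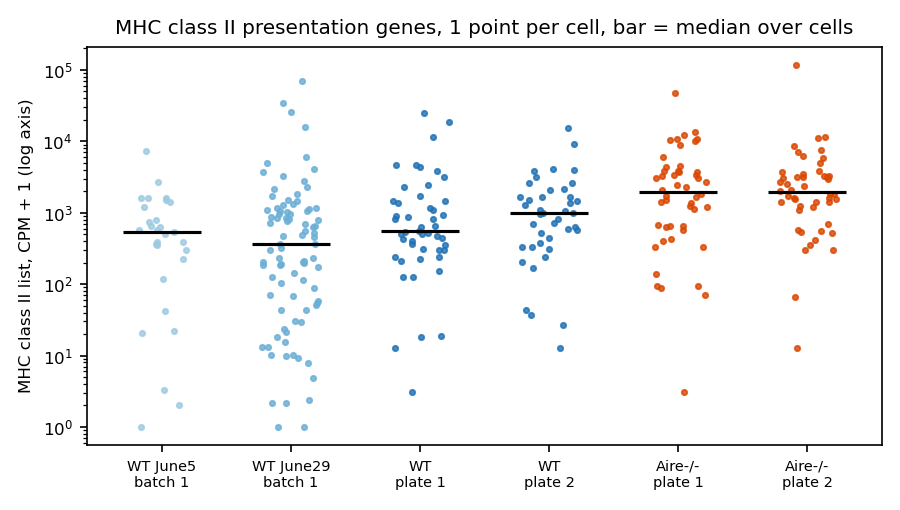
Summed CPM of the 11 MHC class II presentation genes in each cell (1 CPM added, log axis), in the batch 1 sets and by genotype and plate of batch 2, 1 point per cell with a line at the median. Medians for the cells labelled Aire-/- (1964 on plate 1 and 1935 on plate 2) lie above those for WT batch 2 (547 and 975.3), and the highest cell is at 117009.

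The measured genes within 100 kb of Aire on chromosome 10, a window chosen after values were seen, had positive folds, as Aire did. Aire lies at 78030022 to 78043610 on the minus strand of GRCm38, and Dnmt3l, at 78041947 to 78063622 on the plus strand, overlaps it by 1664 bases. Pfkl, the liver phosphofructokinase of glycolysis, at 77986947 to 78010083, was at 177.6 and 462 CPM (log2 fold 1.38) and passed the rule. Icosl, the ligand of the costimulatory receptor ICOS, had a log2 fold of 1.64, and 1810043G02Rik one of 1.03, and neither passed. All 4 measured genes within 100 kb of Aire were positive, with a median of 1.51, while 0 of 11 genes between 0.1 and 1 Mb passed the rule, with a median of 0.33. Of 20 cells labelled Aire-/- with 5 or more Dnmt3l reads, 15 held Aire reads, against 24 of the 76 others.

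**Figure D4:**
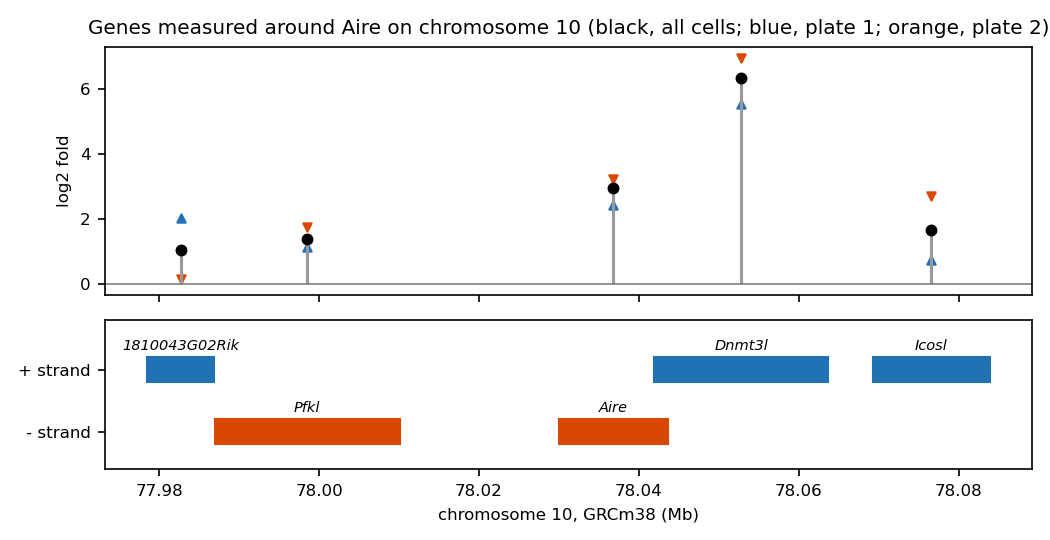
Genes around Aire on chromosome 10 (GRCm38, Mb), drawn by strand, with the log2 fold of each measured gene in cells labelled Aire-/- over WT batch 2 above (circles for all cells, triangles for each plate). Dnmt3l (6.32), Aire (2.95), Icosl (1.64), Pfkl (1.38) and 1810043G02Rik (1.03) are all positive.

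Glycolysis enzymes had a higher list median in the cells labelled Aire-/-, in a list added after Pfkl and others had been seen. The list is thus not independent evidence of its direction. Tpi1 (476 to 1099.9 CPM, log2 fold 1.21), Ldha (314 to 720.2, 1.19), Pgk1 (89.3 to 252, 1.49) and Pfkl passed the rule. Eno1 (1.24), Aldoa (0.99), Gapdh (0.99), Pkm (0.94) and Pgam1 (0.87) did not pass. The list median was 0.87, at percentile 100, with 0.93 on each plate, and 14 of 19 members were positive. Over the 9 members with under 5% of their words in other genes the median was -0.0010, with 4 above 0. All members with more shared words were positive, so the higher list median rests mostly on those members. Between wild-type sets the list median was -0.50 for June29 against June5, 0.37 for WT batch 2 against June5 and 0.71 for WT batch 2 against June29. The brain and muscle enolase genes Eno2 (-1.52) and Eno3 (0.09) and the hexokinase gene Hk1 (-0.0010) were not higher.

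Tuft core genes had a median log2 fold of 0.01, with 15 of 30 members positive, and taste transduction had 0.16, with Calhm3, a subunit of the taste cell channel for ATP release, past the rule (213 to 430 CPM, 1.01). Without its highest cell Calhm3 was at 0.86 and no longer passed. Alox5, the first enzyme of leukotriene synthesis, was at 1299.7 and 2369 CPM and Ptgs1, of prostaglandin synthesis, at 449 and 753, both without passing the rule, and the eicosanoid list had a median of 0.13. Dissociation stress genes were lower together (median -0.68, percentile 0, 13 of 14 members negative, -0.82 and -0.32 by plate), with the immediate early genes Fos (2240 to 1023 CPM), Junb (1672 to 990.4) and Egr1 (539 to 310.3) among them and none past the rule. Cytokines and chemokines were called at 0.81 (0.48 and 0.53 by plate, 0.45 by the mean of per-cell CPM, and -1.71 for WT batch 2 against June29), with Il10 at 238 and 280.3 CPM and Cxcl16, a chemokine for lymphocytes, at 34.4 and 65.4. MHC class I presentation was called at 0.36, led by H2-D1 (7511 to 9885 CPM), and was not called without its highest cell (0.14). Aire-expressing mTEC markers were called at 1.77 (0.36 and 3.73 by plate), with only Aire past the rule, Tnfrsf11a, which encodes RANK, at 15.3 and 32.3 CPM, and Fezf2 at 29.7 and 19.8. A single cell held 48.1% of that list's reads in the set labelled Aire-/-, and the median was 1.67 without it, 1.16 without the cell richest in MHC class II reads and 0.81 without cells with haematopoietic markers. The male list was called at -4.83 (-4.46 without the cell with most of its reads, and still called), and the female list, which is Xist, was at 0.62.

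**Figure D5:**
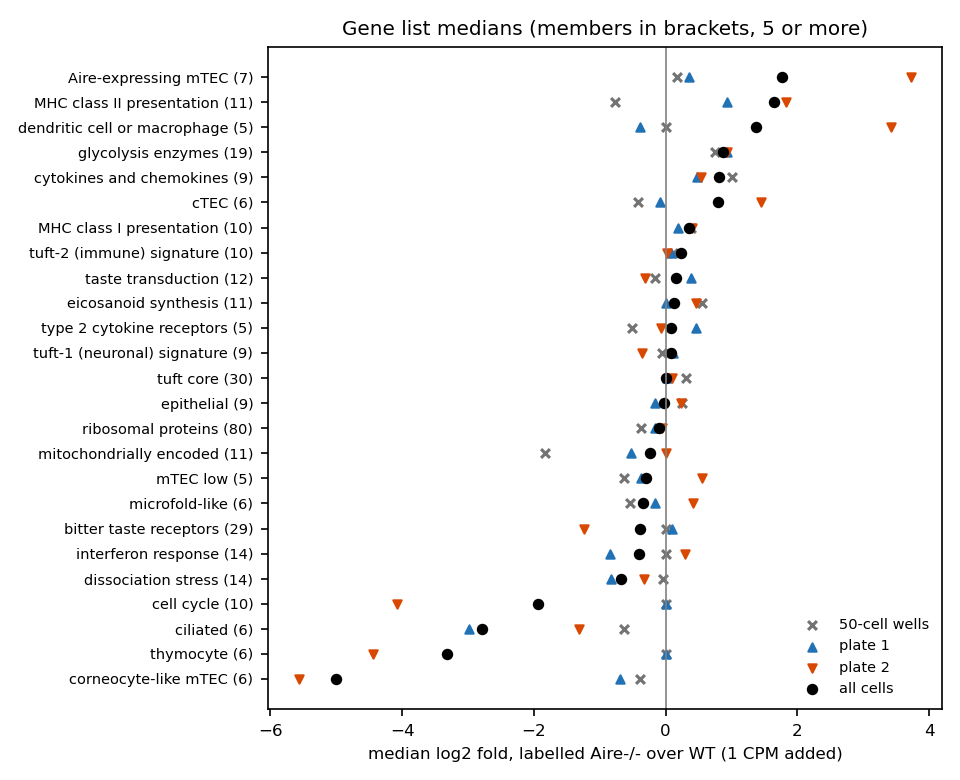
Median log2 fold of each gene list with at least 5 members at the level, cells labelled Aire-/- over WT batch 2 (circles), with the median on each plate (triangles) and in the 50-cell wells (crosses). MHC class II presentation (1.65) and glycolysis enzymes (0.87) are positive on both plates, and dissociation stress (-0.68) is negative on both, while the 50-cell wells have MHC class II presentation at -0.76.

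Several further lists were called, but not once the cell with most of their reads in the set with the higher level was left out. Corneocyte-like markers were called at -5.00, and 80.7% of their reads in WT batch 2 lay in 1 cell with Ivl, a protein of the cornified envelope. Thymocyte markers (-3.32), cell cycle genes (-1.94) and ciliated markers (-2.78) were called with 48.8%, 52.2% and 29.2% of the WT batch 2 reads in 1 cell each. Neuroendocrine-like markers (1.65) and dendritic cell or macrophage markers (1.38) were called with 38.8% and 34.4% of the Aire-/- labelled reads in 1 cell each. Without that cell the medians over the former members of these 6 lists were -0.76, -0.29, -0.07, -1.77, -0.62 and 0.78 in turn. Over the members still at 5 CPM, on which the call rests, they were -2.33, -0.77, -0.14, -1.23, 0.54 and 0.78, at percentiles 3.91, 11.6, 52, 4.58, 79.3 and 93.6. The ciliated list was negative on both plates (-2.98 and -1.32), and at -0.40 against WT batch 2 cells with Xist and no Y reads. Bitter taste receptors were called at -0.39 with 0.10 and -1.24 by plate, and interferon response at -0.40 with -0.85 and 0.30. Without their highest cell these medians were -0.19 and -0.34 (-0.30 over interferon members still at 5 CPM), and that of ribosomal proteins, called at -0.09, was -0.06. Mitochondrially encoded genes were called at -0.24, and still without their highest cell (-0.20). Lists not called were mTEC low (-0.30), cTEC (0.79), microfold-like (-0.35), B cell (-0.20), fibroblast (-2.53), endothelium (-1.07), epithelial (-0.03), Aire-dependent tissue antigens (-0.01), Aire-independent tissue antigens (-0.09), tuft-1 (0.08), tuft-2 (0.24), type 2 cytokine receptors (0.08) and nicotinic and acetylcholine genes (0.22). Of the 13 Aire-dependent antigens in the tables, such as the milk protein gene Csn2, only 4 reached 5 CPM in either set, so that median rests on 4 genes. Without 1 WT batch 2 cell that held 27.4% of their reads the median was 0.94, at percentile 97.6, and the list was called. With members at 0 taken at the limit of 3 reads, the thymocyte median was -3.29 and that of Aire-independent antigens -0.13, and the other list medians did not move.

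Clustering of the 301 kept cells gave 7 clusters, and each had 19 or more tuft core genes in at least 50% of its cells, so none was named as another cell type. Cluster 3, with 51 cells from all 4 sets, was led by Flrt3, Bex4, Rgs21, Bex1, Tas2r129 and Stx19, and its median cell had reads of 16 Tas2r genes. Cluster 4, with 32 cells, was led by H2-DMb2, Ebi3, Serpinb9, Cd52, H2-Ab1 and Pde4b. Cluster 5, with 62 cells from batch 2 alone, was led by Adh1, Il9r, Lypd1, S100a6, Fam19a1 and Itch. Cluster 1, with 47 cells of which 63.8% were WT batch 2, was led by Otud7b, Igfbp5, A330023F24Rik, Colq, Mlec and Tppp3. Cluster 2, with 34 cells and a median of 6404 genes, was led by Kpna6, Gpld1, Plch1, Arf2, Unc5b and Ankrd22. Clusters 6 and 7 drew 68.8% and 72.9% of their cells from June29 and had median mitochondrial shares of 11.5% and 12.6%. Ccl21a, Acta1, Tas2r121 and Ttn led cluster 6, together with a pair of genes without a symbol, and Gm10801, Gm10717, Gm26870, Gm10719, Gm10800 and Gm10718 led cluster 7. No batch correction was made, so a cluster made mostly of 1 set cannot be told apart from that set.

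The 50-cell wells, with 539621 gene reads for Aire-/- and 720527 for WT, gave a further pair of libraries from the same batch. Their genotypes here are those of their titles and of the count tables that hold them, while the deposited notes on each well name the count table of the other genotype. If the wells were exchanged, the sign of every fold of this pair would turn. The WT well held 33 Y-linked reads and the Aire-/- well 0. Aire stood at 25.9 CPM in the Aire-/- well and 15.3 in the WT well, and Dnmt3l at 35.2 CPM and 0. The stress, glycolysis and MHC class II lists had medians of -0.04, 0.75 and -0.76 there. Cd74 stood at 4515 CPM in the WT well and 1710.5 in the Aire-/- well, opposite to the single cells. Over 8267 genes the folds of the 50-cell pair and of the single cells correlated at 0.0603 across genes, and of the 84 higher and 33 lower genes 54 and 25 had the same sign in the 50-cell pair. The no-cell well of batch 1 held 9892 gene reads and 3272929 spike-in reads, which were 99.7% of its reads.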

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

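The tests that leave out the cell with the most MHC class II reads or cells with Aire-expressing mTEC markers, that compare MHC class II genes with Xist-positive wild-type cells, and that use the median cell, with markers at 1 read, were chosen only after the results were seen.

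MHC class II genes had a list median log2 fold of 1.65 in single cells labelled Aire-/- (0.94 and 1.82 by plate) and of -0.76 in the 50-cell pair as titled, opposite to both plates, a difference that was not tested. The sex composition of the sets as the cause is argued against by the median of 2.12 over wild-type cells with Xist and no Y reads. Cells with 2 or more haematopoietic markers at 1 read, as the whole cause of the difference in the median cell, are argued against by its log2 ratio of 1.56 without them, against 1.44 with them. That broad filter left 47 WT batch 2 and 56 Aire-/- labelled cells. The interval of 0.79 to 2.49 lies above the bound of 0.72, which was set afterwards. It comes from 10000 draws of the cells of each pool and does not cover differences between pools. For the summed reads, the list median was 0.89 without cells with haematopoietic markers, a type the CD45- and CD11c- gates should remove. It was 0.94 without the 5 WT batch 2 and 16 Aire-/- labelled cells with Aire-expressing mTEC markers. Without the cell richest in these reads it was 0.81, or 0.90 over the 10 members still at 5 CPM. These tests are not separate, since that cell, whose own type is not known, holds both kinds of markers. With only it put back the medians were 1.84 and 1.89, not below the 1.65 over all cells. This argues against the other cells with either kind of markers as the cause of the higher list median. The reads of that 1 cell stay open, and with them both cell types as far as it belongs to either. Cells with fewer markers were not covered. The genotype label also stays open and untested, as it goes with the set of wells.

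Aire was higher in cells labelled Aire-/-, against what a loss of Aire transcript would give, as were 2 of 4 measured genes within 100 kb, a window chosen after values were seen. Of the tests here, only that of a long strain segment went against its explanation, and only in part. Aire-expressing mTEC in the sort, a type the MHCII low gate should mostly remove, would bring their other markers, whose median was 1.71 against 2.95 for Aire, but 0.18 against 2.44 on plate 1 and 4.08 against 3.22 on plate 2, and 1 cell of plate 2 held 75.5% of the Ciita reads of the set. Reads of an Aire transcript counted at the overlapping Dnmt3l stay open, since 75% of Dnmt3l-positive cells held Aire reads (interval 50.9 to 91.3), between the 50% and 80% set beforehand. A long strain segment linked to the targeted allele was predicted beforehand to put at least 3 times the share of all genes past the rule at 1 to 5 Mb. Without it, at most 1.5 times that share was predicted. The share was 0% of 86 genes against 1.42% over all genes, which argues against a segment of that effect. Its upper limit of 3.49% lies below 3 times that share, but above 1.5 times it, a bound that 86 genes could not reach. The rule also found few simulated 2-fold changes, so a segment with smaller effects stays open. The genotype itself, including an altered but still transcribed Aire allele, was not tested and cannot be told apart from the set of wells.

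Glycolysis enzymes had a list median of 0.87 in cells labelled Aire-/- and 0.93 on each plate. Sex composition is argued against by a median of 1.04 over wild-type cells with Xist and no Y reads. More RNA per cell was judged on the wild-type plates, which differed in gene reads per spike-in read by 0.35 on the log2 scale (0.58 between genotypes). The list median towards the plate with more was -0.060, under 0.25 of the genotype median, the bound written beforehand for evidence against this cause. Its interval of -0.54 to 0.41, from the ranked folds of 19 genes that are not independent, reaches above that bound. The plates also differ by less than the genotypes, so a smaller effect of RNA amount stays open. Reads shared between gene copies stay open, since the 9 members with few shared words had a median of -0.0010 with 4 of them above 0. All members with more shared words were positive, so the higher list median rests mostly on those members. The cause was read as open because members with few shared words went both ways. The genotype label was not tested apart from the set of wells.

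The sign of the 50-cell folds rests on which well is which, since the deposited notes on each name the count table of the other genotype, while titles and tables give the genotypes used here. Y-linked reads numbered 33 in the WT well and 0 in the Aire-/- well. Eif2s3y stood at 33.3 CPM in the WT well. In single cells of the same batch it stood at 30.9 CPM in wild type and 0.028 in those labelled Aire-/-. Uty was lower in the WT well, at 5.55 CPM against 36.3 in wild-type single cells. These reads argue against an exchange, if the wells held cells of the same pools. The median of the MHC class II list, opposite to the single cells, goes the other way, though its members H2-DMa, H2-Oa and Ctss do not. Aire and Dnmt3l were higher in the Aire-/- well, as in the single cells, which goes with the titles. The no-cell well of batch 1 held 9892 gene reads, above the limit that a count of 0 allows, with 10.4% of them on Slc34a2. Ccl25, a chemokine for thymocytes made by cortical epithelium, stood at 436 CPM in the WT 50-cell well against 0 in the no-cell well and 18.5 in the Aire-/- 50-cell well, which were outside the single-cell comparisons.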

How the results depend on the processing

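The alternatives with Xist-only wild-type cells as the reference, wells of the score table, other mitochondrial limits, cells without haematopoietic markers for lists and MHC class II genes, the set without the cell richest in MHC class II reads, and clusters without selected genes were chosen only after the data were seen. No paired analysis was possible because no cell is paired with another. Both plates hold both genotypes, and folds within each plate are given. The genes higher in cells labelled Aire-/-, 1.02% of 8267, came to 1.65% with the mean of per-cell CPM, 2.65% on plate 1, 3.73% on plate 2, 2.21% against the median of the 3 wild-type sets and 3.27% against WT batch 2 cells with Xist and no Y reads, all as a percent of those 8267. The lower genes, 0.399%, came to 0.181% at a minimum of 50 CPM, 0.847% with 1 read for a positive cell, 0.254% with 20 reads, 1.46% and 1.32% on plates 1 and 2, 0.629% without cells with haematopoietic markers, 1.802% against the 3 wild-type sets, 0.944% against Xist-only cells and 0.677% with at most 10% mitochondrial reads. The cause of these moves was not tested. Of the 84 higher and 33 lower genes, 45 and 12 still passed against the 3 wild-type sets, the fewest of any alternative, with 12 of the lower also at 20 reads. Against Xist-only cells 60 and 16 passed, on plate 1 51 and 24, on plate 2 53 and 19, without haematopoietic cells 60 and 23, and without the cell richest in MHC class II reads 76 and 32. Over 22 alternatives, 601 of 660 folds of Il25 and the 29 named genes past the rule moved by less than the spread between plates, 56 moved by more and 3 reversed, namely Uty (0.059) and Eif2s3y (0.039) against Xist-only cells, by the choice of cells without Y reads, and Tfrc (-0.13) against the 3 wild-type sets. Part of the 601 was fixed in advance, since CPM filters and read limits for a positive cell enter the rule but not the fold. A minimum of 500 genes kept the same cells, and plates 1 and 2, which set the spread, were themselves alternatives. Of 363 list medians over 11 alternatives, 57 moved, 9 medians of the 17 called lists reversed, and 44 medians of the 16 lists not called had the opposite sign, which is not counted as reversed. Against Xist-only cells the corneocyte-like list was 0.048, bitter taste receptors 0.20 and the male list 0.049. On plate 1 the neuroendocrine-like list was -0.57, dendritic cell or macrophage -0.39 and bitter taste receptors 0.10, on plate 2 interferon response was 0.30 and mitochondrially encoded genes 0.0085, and without haematopoietic cells the neuroendocrine-like list was -0.36. The MHC class II median moved to 0.94 on plate 1, 0.89 without haematopoietic cells and 0.81 without the richest cell, and the log2 fold of its summed level, 1.68, to 0.84 without that cell. With 5 reads the median Tas2r count was 2 in June5, 2 in June29 and 3 in cells labelled Aire-/-, and thinned June29 cells had 3. The share of cells with haematopoietic markers was 68.97%, 67.8%, 47.2% and 41.7% in the 4 sets with 1 read per marker, and 3.45%, 4.60%, 3.37% and 3.13% with 3 markers at 5 reads. After thinning, June29 against June5 had 1.11% of genes higher and 9.01% lower and WT batch 2 against June29 had 7.20% higher. Clusters numbered 4 at a resolution of 0.5, and the correlation with the 50-cell pair was 0.0981 over 4442 genes at 50 CPM or more. At these depths the size rule found few simulated changes in reads per positive cell, so such differences can be missed.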

Other observations

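The tests in this part on the cell with the most MHC class II reads and on clusters made without selected genes were chosen only after the results were seen.

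One cell labelled Aire-/- on plate 2 differed from the rest of its set. It had 1885083 gene reads and 5975 genes, 6 of the 8 Aire-expressing mTEC markers and 21 of the 30 tuft core genes at 5 or more reads. MHC class II genes made up 117009 CPM of its reads, and it held 43.4% of the Aire reads, 75.5% of the Ciita reads and 44.6% of the Cd40 reads of its set. Ciita encodes the activator of MHC class II genes and Cd40 a costimulatory receptor. Trpm5 stood at 149.07 CPM in it against 1985 in the other cells, and Pou2f3 at 1.06 against 468. Of the 32 cells labelled Aire-/- with 5 or more Aire reads, 5 had at least 2 other Aire-expressing mTEC markers (15.6%, interval 5.28 to 32.8), against 5 of 64 without (7.81%).

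With the 51 Tas2r and MHC class II genes left out, clustering again gave 7 clusters. In the cluster led by Flrt3, Bex4 and Bex1, with 19 cells of WT batch 2 and 24 labelled Aire-/-, MHC class II genes stood at 968 and 2117 CPM, and at 815 and 1728 without the cell with most of these reads in each set. In the cluster led by Igfbp5, Mlec and A330023F24Rik, with 34 and 13 cells, they stood at 1903 and 1648 CPM, and without those cells at 1200.03 and 1337, the other way round. In the cluster led by Adh1, Lypd1 and Il9r, with 20 and 33 cells, they stood at 2354 and 6063 CPM, and without those cells at 1618 and 4772. In the cluster led by H2-DMb2, Ebi3 and Serpinb9, with 8 and 20 cells, they stood at 4978 and 14496 CPM, and without those cells at 2608 and 3265.

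The labels describe wells of 50 cells where the series text speaks of 100 cells, and the deposited notes on each of these wells name the count table of the other genotype. The well of June29 labelled as no-cell is listed as wild type in the deposited table of wells. The summed level of mt-Rnr2, the mitochondrial ribosomal RNA, was 30093 CPM in June29, 22393 in June5, 20627 in WT batch 2 and 16192 in cells labelled Aire-/-.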
